A study of Mus musculus with 20 samples.

How the data were processed

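Total RNA from 20 samples of bone-marrow-derived mouse eosinophils was turned into biotin-labelled cRNA with the Affymetrix 3' IVT Express kit, per the labels, and hybridised to one-colour arrays. The authors deposited 1 table of log2 expression values, 20630 probe sets by 20 arrays. The unit was read from the values: they ran from 1.27 to 13.99 with near-equal medians on all arrays, beyond what a natural log of a scanner value could reach. The background correction, summarization and normalization behind the table, and how its probe sets were chosen from the platform's, are not given in the sources used here. Values were used as deposited, so differences between genotypes depend on whatever between-array scaling the authors applied.

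Gene names came from the platform annotation. Leaving out 2 control probe sets, 17826 probe sets had exactly 1 gene symbol, 91 had several and 2711 had none in it; 17675 of the first kind were matched by gene number to a mouse RefSeq gene table (assembly GRCm38.p6), which gave current symbols and neighbouring genes. No genome build is stated for the array, so no coordinates are printed. The 17826 probe sets stood for 17771 genes. For 54 genes with more than 1 probe set, the one with the highest mean over all arrays was used. A gene was tested when its value exceeded the array's 40th percentile, which lay between 3.56 and 3.68, on at least 5 arrays, which left 11767 genes. Where the dimmer group of a named gene lay on average below that percentile, the fold with IL-33 is given as a lower bound, with each array under its percentile set to it. The percentile stands in for a background level, which the table does not give. Il1rl1, the gene of the IL-33 receptor, is not analysed here.

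The groups came from the genotype and treatment labels. All 20 arrays entered a linear model with 1 mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 16 residual degrees of freedom), which gave IL-33 against untreated in each genotype, knockout against wild type in each treatment, and the interaction. Adjusted p is Benjamini-Hochberg over the 11767 genes of a comparison, and a gene was called at an adjusted p under 0.05. The model, the gene filter, the gene lists and the alternatives were chosen before the data were examined, except where an alternative is said to have been added. On simulated data with 100 genes changed per size, the fit recovered 77% of changes of 0.5 and 97% of changes of 1 on the log2 scale in the genotype comparison after IL-33. The same sizes gave 38% and 86% in the interaction and 72% and 98% in the IL-33 comparison in knockout cells. Of the unchanged genes 11, 4 and 7 were called in these comparisons, in the order given. The simulated noise was independent for each gene and array, with no mouse effect and no factor shared by genes. The rates therefore do not give the power on the real arrays, where such structure is present.

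The text names, per comparison, genes among the 10 largest called rises and 10 largest called falls, up to 4 called members of each list with the largest change, up to 2 members of a list with no call, and always Dusp5, Bcl2l1, Mcl1, Bcl2, Dusp6, Epx, Prg2, Siglecf, Ccr3 and Il5ra. Nnt, Mxi1 and Smc3, neighbours of called genes, were chosen after their values were seen.

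The 30 fixed lists covered ERK output and feedback, other MAP kinase phosphatases, anti-apoptotic and pro-apoptotic Bcl2 family genes, cytokines, chemokines, NF-kB targets and feedback, IL-33 receptor and signalling, eosinophil granule proteins, eosinophil identity and receptors, and adhesion and surface activation. Others covered eicosanoid synthesis and receptors, tissue remodelling, type 2 activation, STAT feedback and targets, interferon-stimulated genes, proliferation, glycolysis, the unfolded protein and integrated stress response, cholesterol synthesis, and NADPH oxidase and antioxidants. The rest held markers of neutrophils, of monocytes, macrophages and dendritic cells, of mast cells and basophils, of lymphocytes, of erythroid cells and megakaryocytes, of stem and progenitor cells and of stromal and endothelial cells, neighbours of Dusp5 within 10 Mb, and sex-linked check genes. Of these, 29 had at least 3 tested members and were tested with camera (preset correlation 0.01), adjusted over the 29. Genes of a list can move together, so the p with a correlation estimated per list is given beside each call. Differences between genotypes in list means and in the response score were also tested by exact two-sided permutation over the 10 mice (252 assignments).

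Replicate numbers are shared between the groups. The series text names 5 mice per genotype, and the pairing was checked by the correlation of deviations from the group means. Untreated and IL-33 arrays of the same number and genotype correlated at 0.262 to 0.783, all 10 best with their own number, so the number was taken to mark the mouse. Within groups, arrays correlated at 0.976 to 0.996, and no pair of arrays held identical values. Alternatives with the mouse as a random block (duplicateCorrelation, correlation 0.464, with cameraPR for lists) or a fixed block, other filters, scalings, array weights, probe set rules, subsets of arrays and thresholds were run, and their effect is given in the closing section. No scan date or batch is given in the sources used here. Probe sets with no gene name or several were left out of the gene comparisons.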

Results

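Messenger RNA levels were measured in eosinophils grown from mouse bone marrow, the granulocytes of allergic inflammation, which carry the receptor for the alarm cytokine IL-33. The cells came from mice with Dusp5 (Dusp5+/+, wild type) and mice without it (Dusp5-/-, knockout), 5 of each genotype. Dusp5 encodes a nuclear phosphatase that removes the activating phosphates from the MAP kinases ERK1 and ERK2, and its own gene is switched on by ERK signalling. On day 12 of culture, cells of each mouse were left in medium or given 25 ng/ml IL-33 for 4 hours. The 20 one-colour arrays, 1 per sample, thus fell into 4 groups of 5. The median log2 value per array lay between 4.25 and 4.32, and the number of arrays limits the precision of each value. Of 17771 genes with an unambiguous probe set, 11767 were bright enough to be tested. The first principal component held 62.2% of the variance and parted all 10 untreated from all 10 IL-33 arrays. Changes are given as log2 differences ± SE of the limma fit with 5 arrays in each group, and levels as the mean ± SD of 5 arrays.

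The targeted transcript was low on every knockout array. The Dusp5 level was 8.15 ± 0.26 (SD, n = 5) in untreated wild-type cells and 4.40 ± 0.31 in untreated knockout cells. After IL-33 it was 9.77 ± 0.35 in wild-type and 4.95 ± 0.18 in knockout cells. The highest knockout array reached 5.15 and the lowest wild-type array 7.85, so no array went against its genotype label. Knockout cells thus held 13.5-fold less Dusp5 signal than wild-type cells untreated (log2 difference -3.76 ± 0.17) and 28.3-fold less after IL-33 (-4.82 ± 0.17). Which part of the gene was deleted is not given in the sources used here, and a probe set of the 3' end can lie outside it, in which case the signal does not check the deletion. The gene lies on chromosome 19 in the GRCm38.p6 assembly.

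**Figure D1:**
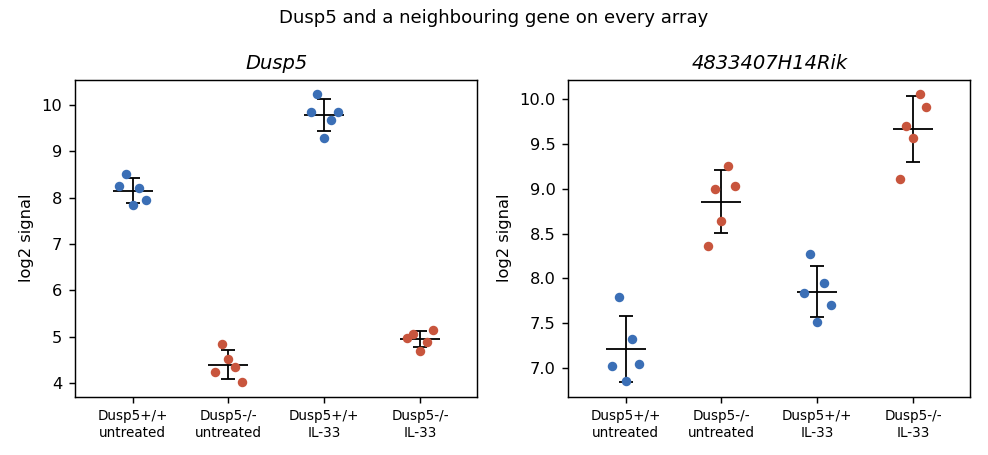
Log2 signal of Dusp5 and of the neighbouring gene 4833407H14Rik on each of the 20 arrays, by group, with the mean and SD of 5 arrays. For Dusp5, all 10 knockout arrays sit at or below 5.15 and all 10 wild-type arrays at or above 7.85.

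The first comparison asked what IL-33 does to normal eosinophils. In wild-type cells, 4 hours of IL-33 raised inflammatory mediators the most. Ptgs2, the inducible cyclooxygenase, rose by 8.06 ± 0.25 on the log2 scale. Its untreated level of 3.18 ± 0.69 (SD, n = 5) lay below the percentile of the dim filter on 4 of 5 arrays, and with those arrays set to that percentile the rise was at least 185-fold. The neutrophil chemoattractant Cxcl2 rose by 6.48 ± 0.23, the cytokine Il1b by 6.22 ± 0.18 and the NF-kB cofactor Nfkbiz by 5.80 ± 0.13. The early activation marker Cd69 (5.66 ± 0.16), the survival kinase Pim2 (5.59 ± 0.12), Il6 (5.06 ± 0.10), the lipid phosphodiesterase Smpdl3b (4.87 ± 0.17), the itaconate-producing enzyme Acod1 (4.41 ± 0.14) and Il1a (4.14 ± 0.22, at least 15.2-fold by the same bound) completed the 10 largest fitted rises. The falls were smaller. Pik3ip1, an inhibitor of PI3 kinase, fell by 2.69 ± 0.18, Sncaip by 2.26 ± 0.20 and the semaphorin Sema4f by 1.96 ± 0.18. Chdh (choline dehydrogenase), the oxysterol-binding Osbpl5, Cnnm2, the Rac activator Tiam2, the ubiquitin ligase subunits Fbxo31 and Fbxo32 and the Wnt receptor Fzd2 fell by 1.85 to 1.95.

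In all, 5027 of the 11767 genes (42.7%) passed an adjusted p of 0.05 in limma, of which 1890 rose and 3137 fell. At least 2-fold changes were fewer, 316 rises and 194 falls. Dusp5 itself rose 3.08-fold (1.62 ± 0.17, adjusted p = 1.4e-07).

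Gene groups fixed before the data were examined moved together. All 19 tested NF-kB targets and feedback genes rose, among them the RNase Zc3h12a (3.81 ± 0.13) and the receptor adaptor Traf1 (2.72 ± 0.15). In the group of STAT feedback and target genes, 8 of 9 rose, led after Pim2 by the cytokine-signalling inhibitors Socs3 (3.92 ± 0.17) and Cish (2.87 ± 0.12) and the kinase Pim3 (2.68 ± 0.15). Of 15 chemokines 11 rose and 1 fell; Cxcl3 rose by 3.99 ± 0.29, Ccl4 by 3.41 ± 0.14 and Ccl7 by 3.24 ± 0.12. Of 16 cytokines 10 rose, including the type 2 cytokine Il13 (3.58 ± 0.24). Of 4 anti-apoptotic Bcl2 family genes 3 rose (4 adjusted over the list alone): Bcl2 (1.37 ± 0.18), Bcl2l1, which encodes Bcl-xL (1.19 ± 0.09), and Bcl2l2 (0.38 ± 0.10). The remaining member Mcl1 stood at 0.33 ± 0.15, with adjusted p = 0.084, and passed with each mouse as a random block (adjusted p = 0.00528) and without untreated wild-type array 2 (0.0170) or IL-33 wild-type array 3 (0.0476). These 5 lists shifted upward in camera's test with its preset correlation, with adjusted p from 7.9e-28 for NF-kB to 0.00328 for the anti-apoptotic list, and they kept adjusted p between 5.6e-04 and 0.0432 with an estimated correlation.

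A further 5 lists passed camera with the preset correlation and not with an estimated one. Of 19 ERK output and feedback genes 12 rose and 2 fell (adjusted p = 5.1e-08; adjusted p = 0.070 with an estimated correlation). Phlda1 (3.06 ± 0.13), the immediate-early transcription factors Egr3 (2.80 ± 0.27) and Egr2 (2.54 ± 0.15) and the survival gene Ier3 (2.29 ± 0.08) led them. Dusp6, the cytoplasmic ERK phosphatase, rose by 0.65 ± 0.23 (adjusted p = 0.027), a call lost without untreated wild-type array 1, 3 or 5 or IL-33 wild-type array 2 (adjusted p up to 0.0856). Of 13 NADPH oxidase and antioxidant genes 12 rose (adjusted p = 5.1e-08; adjusted p = 0.070 with an estimated correlation). The largest were the antioxidant genes Srxn1 (1.80 ± 0.14), Hmox1 (1.62 ± 0.12), Slc7a11 (1.59 ± 0.15) and Txnrd1 (1.42 ± 0.10). Of 10 type 2 activation genes 8 rose, or 9 adjusted over the list alone (adjusted p = 2.7e-07; adjusted p = 0.070 with an estimated correlation), among them Arg1 (3.44 ± 0.21) and the inhibitory ligands Pdcd1lg2 (1.65 ± 0.10) and Cd274 (1.34 ± 0.09).

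In the adhesion and surface activation list 7 of 16 genes rose and 3 fell (adjusted p = 0.0107; adjusted p = 0.577 with an estimated correlation). The risers beside Cd69 were Icam1 (1.68 ± 0.10), Cd40 (1.33 ± 0.10) and Cd80 (1.30 ± 0.13), while the list's median change was 0.06. Of 9 other MAP kinase phosphatases 5 rose and 3 fell (adjusted p = 0.0293; adjusted p = 0.251 with an estimated correlation and 0.0522 with each mouse as a fixed block). Dusp16, which acts on JNK and p38, rose by 2.65 ± 0.10, and Dusp1 fell by 0.71 ± 0.14.

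The remaining lists did not pass camera in the main fit (adjusted p of 0.0572 or more), although single members changed. With no dim filter pro-apoptotic genes (adjusted p = 0.0395), IL-33 receptor and signalling (0.0487), proliferation (0.0452) and stem and progenitor markers (0.0452) passed camera. IL-33 receptor and signalling also passed with the filter at the 60th percentile (0.0453) and with quantile normalization (0.0364). Of 9 pro-apoptotic Bcl2 family genes 3 rose, Bmf (2.18 ± 0.16), Bcl2l11, which encodes Bim (1.63 ± 0.13), and Pmaip1 (1.18 ± 0.07), and Bbc3 fell (-1.05 ± 0.08; list adjusted p = 0.0624, and 0.0174 with each mouse as a random block). Of 11 IL-33 receptor and signalling genes 7 rose and 2 fell (adjusted p = 0.0572, and 0.0271 with the random block), with the inhibitory kinase Irak3 at 2.29 ± 0.11 and the inhibitory receptor Sigirr at -0.60 ± 0.09. None of the 4 tested granule protein genes passed in limma; Epx, eosinophil peroxidase, stood at -0.05 ± 0.18 and Prg2, major basic protein, at -0.00 ± 0.06 (list adjusted p = 0.922). Of 13 eosinophil identity and receptor genes 3 rose and 3 fell (adjusted p = 0.980). The interleukin 5 receptor Il5ra fell by 0.84 ± 0.16 and Siglecf by 0.71 ± 0.15, while the eotaxin receptor Ccr3 was at -0.30 ± 0.35 and passed with each mouse as a fixed block (adjusted p = 0.00754). Eicosanoid genes (6 rose, 4 fell of 16; adjusted p = 0.239, and 0.0462 with the random block), tissue remodelling (3 and 3 of 13, with Hbegf at 2.49 ± 0.17; 0.369), interferon-stimulated genes (4 and 3 of 13, with Gbp2 at 2.55 ± 0.20; 0.254) and glycolysis (7 and 4 of 14, with the glucose transporter Slc2a1 at 1.21 ± 0.08; 0.138) were mixed.

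So were unfolded protein and integrated stress response genes (1 rose and 2 fell of 16, with Ddit3 at -0.69 ± 0.08; adjusted p = 0.829) and cholesterol synthesis genes (2 and 3 of 15, with Insig1 at 1.31 ± 0.24; 0.681). In the proliferation list 0 of 21 genes rose and 4 fell over all genes in limma, 0 adjusted over the list alone (adjusted p = 0.199). With each mouse as a fixed block this list passed (3.1e-06), and its mean changed by -0.487 ± 0.076 (SD, n = 5), lower after IL-33 in all 10 mice of both genotypes. Mcm7, of the replicative helicase, fell by 0.90 ± 0.31, a call lost without untreated wild-type array 3 or 5 or IL-33 wild-type array 2 (adjusted p up to 0.0758). Markers of other cells did not pass camera in the main fit. The camera adjusted p was 0.677 for neutrophil markers (2 of 13 rose, with Chil1 at 2.08 ± 0.15), 0.889 for monocyte, macrophage and dendritic markers (3 rose and 3 fell of 15, with Cd14 at 2.13 ± 0.11) and 0.959 for mast cell and basophil markers (1 and 2 of 8). It was 0.889 for lymphocyte markers (2 and 1 of 5), 0.549 for erythroid and megakaryocyte markers (1 of 7 rose, Car2 at 1.87 ± 0.13) and 0.331 for stromal and endothelial markers (1 of 3 rose). Of 6 stem and progenitor markers 3 fell (adjusted p = 0.0820): Sox4 (-1.06 ± 0.21), Erg (-0.95 ± 0.15) and Hoxa9 (-0.91 ± 0.15). Among 104 neighbours of Dusp5 on its chromosome 16 rose and 37 fell (adjusted p = 0.574), and of the sex-linked check genes only Xist was bright enough to test.

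The same question was asked of knockout cells, in which 6137 genes (52.2%) passed, 2228 of them rises and 3909 falls. The genes at the top were mostly those of wild-type cells: Ptgs2 rose by 8.84 ± 0.25 (at least 341-fold, with 4 of 5 untreated arrays below the percentile of the dim filter), Cxcl2 by 7.01 ± 0.23, Il1b by 6.84 ± 0.18, Nfkbiz by 6.26 ± 0.13 and Cd69 by 6.22 ± 0.16. Pim2 (5.72 ± 0.12), Il6 (5.30 ± 0.10), Il1a (4.98 ± 0.22), Il13 (4.96 ± 0.24) and Acod1 (4.80 ± 0.14) followed. The largest falls were those of Pik3ip1 (-3.10 ± 0.18), Sncaip (-2.64 ± 0.20, at least 5.66-fold with dim arrays set to the percentile) and Osbpl5 (-2.39 ± 0.11). Abhd15, Fbxo31, Fbxo32, Cnnm2, Tmem215, the lipid enzyme Tmem86a and Tsc22d3, the glucocorticoid-induced leucine zipper, fell by 2.11 to 2.33. At least 2-fold changes numbered 373 rises and 358 falls.

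All 19 NF-kB genes, 8 of 9 STAT genes, 11 of 15 chemokines, 11 of 16 cytokines and 3 of 4 anti-apoptotic genes rose in knockout cells, and 1 cytokine fell. These 5 lists passed camera with the preset correlation (adjusted p from 3.2e-24 to 0.00334) and with an estimated one (adjusted p from 0.00121 to 0.0331). The eosinophil-recruiting chemokine Ccl24 rose by 3.37 ± 0.17, Bcl2 by 1.92 ± 0.18 and Bcl2l1 by 1.28 ± 0.09, while Mcl1 stood at 0.30 ± 0.15 (adjusted p = 0.10; 0.00932 with each mouse as a random block). Of 19 ERK output genes 15 rose and 3 fell (adjusted p = 6.5e-09; adjusted p = 0.0653 with an estimated correlation), with Phlda1 at 3.71 ± 0.13, Egr3 at 3.24 ± 0.27, Egr1 at 2.98 ± 0.18, Egr2 at 2.91 ± 0.15 and Dusp6 at 1.08 ± 0.23. NADPH oxidase and antioxidant genes (11 of 13 rose, 12 adjusted over the list alone) and type 2 activation genes (7 of 10) passed with adjusted p of 1.8e-07 and 6.7e-06, which became adjusted p = 0.0993 and 0.0999 with an estimated correlation. The adhesion list had 7 rises and 3 falls of 16 (adjusted p = 0.0243; adjusted p = 0.690 with an estimated correlation and 0.0728 with each mouse as a fixed block). Its mean of 0.68 and the test pointed up while its median was -0.03, which turned to 0.08 with a further quantile normalization.

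The other 20 lists tested in knockout cells had camera adjusted p of 0.0629 or more in the main fit. With no dim filter proliferation (0.0279), stem and progenitor markers (0.0267) and pro-apoptotic genes (0.0456) passed. Proliferation (0.0467) and stem and progenitor markers (0.0476) passed with only the 2 groups compared, and the latter with quantile normalization (0.0499). With each mouse as a fixed block proliferation (mean -0.631 ± 0.090; adjusted p = 1.5e-06) and stem and progenitor markers (-0.830 ± 0.013; 0.0306) passed, and with a random block other MAP kinase phosphatases (0.00735) and pro-apoptotic genes (0.0159). None of the 4 granule protein genes passed in limma, with Epx at -0.08 ± 0.18 and Prg2 at 0.02 ± 0.06, a value whose sign turned with quantile normalization. Il5ra fell by 1.08 ± 0.16 and Siglecf by 0.61 ± 0.15; Ccr3 was at -0.47 ± 0.35 and passed with each mouse as a fixed block (adjusted p = 2.4e-04). The protease inhibitor Timp1 rose by 1.13 ± 0.22, the type 2 marker Retnla by 1.27 ± 0.27, and the progenitor gene Meis1 fell by 0.77 ± 0.20. The remaining Dusp5 signal rose by 0.56 ± 0.17 (adjusted p = 0.0081), a call lost without both arrays of knockout mouse 5 (0.41, adjusted p = 0.0668).

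The responses of the genotypes shared most of their genes. Between the 5027 and 6137 calls, 4577 were the same gene in the same direction, 1610 rises and 2967 falls, against 357.9 and 1042 for independent lists; no gene went in opposite directions. Another 450 genes were called in wild-type cells alone and 1560 in knockout cells alone, and the test of the difference itself is given with the interaction. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.966 and an orthogonal slope of 1.15, knockout on wild type. These comparisons share no arrays. Without members shared between lists, other MAP kinase phosphatases, which then lack Dusp6, lost their calls in camera for IL-33 in wild-type cells (adjusted p = 0.199) and for the genotype untreated (0.133) and after IL-33 (0.183), and adhesion lost its calls for IL-33 in wild-type (0.0552) and knockout cells (0.0821; 0.0526 with the filter at the 60th percentile). Camera compares a list with other genes. In a test of each list's own mean within mice, chosen after the data were seen, 27 of 29 lists passed for IL-33 over both genotypes (exact sign-flip over 10 mice, adjusted p from 0.00258), and neutrophil markers (0.377) and monocyte, macrophage and dendritic markers (0.0809) did not.

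**Figure D2:**
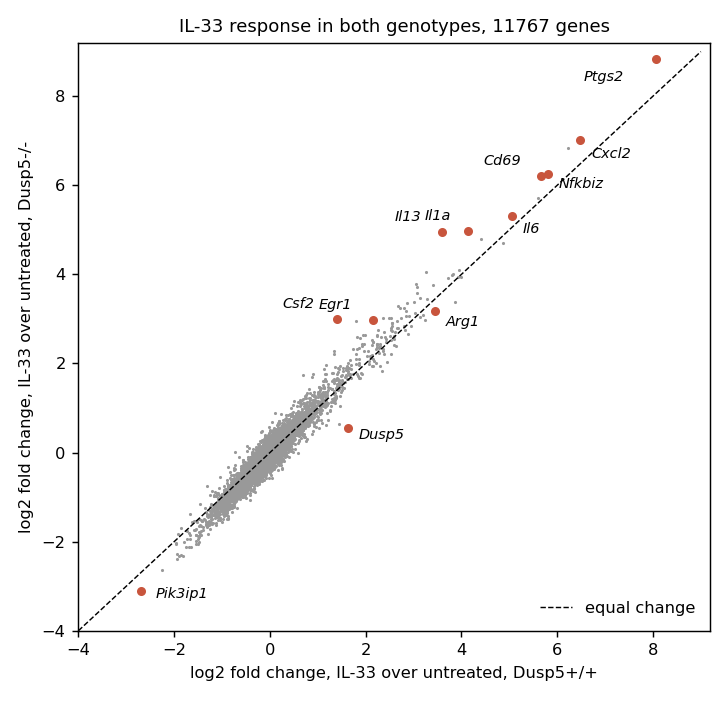
Log2 change with IL-33 in wild-type cells (horizontal) and knockout cells (vertical) for 11767 genes, with the line of equal change dashed. The points follow a slope of 1.15, steeper than the dashed line, and Dusp5 lies below that line.

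The genotypes were next compared in untreated cells, which asks what loss of Dusp5 does at rest. Apart from Dusp5 (-3.76 ± 0.17), limma called 2 genes, both higher in knockout cells. The non-coding 4833407H14Rik, which neighbours Dusp5 on chromosome 19, was higher by 1.65 ± 0.20, and Tmem267, a membrane protein gene on chromosome 13, by 1.44 ± 0.18 (adjusted p = 4.2e-04 each). In both treatments Tmem267 lay between 3.72 and 3.95 on wild-type arrays and between 4.66 and 5.91 on knockout arrays. The wild-type values are close above the percentile of the dim filter, so the size of its difference is uncertain. The early growth response genes did not pass, with Egr3 at 1.16 ± 0.27 (adjusted p = 0.31; 0.0237 without untreated wild-type array 2) and Egr1 at 0.68 ± 0.18 (0.38). Survival and identity genes did not pass either: Bcl2 0.08 ± 0.18, Bcl2l1 0.12 ± 0.09, Mcl1 0.30 ± 0.15, Dusp6 0.53 ± 0.23, Epx -0.18 ± 0.18, Prg2 -0.06 ± 0.06, Siglecf 0.15 ± 0.15, Ccr3 0.71 ± 0.35 and Il5ra -0.25 ± 0.16. Untreated Bcl2 lay around the percentile of the dim filter, at 3.22 to 4.07 in wild-type and 3.59 to 3.96 in knockout cells. A difference at rest could thus be missed, and the changes of Bcl2 with IL-33 start from that level. Cell division genes were lower without passing singly in the main fit (Mki67 -0.94 ± 0.37, Rrm2 -0.92 ± 0.38). Both passed in limma with array weights (adjusted p = 0.0371 and 0.0334). All 21 genes of the proliferation list had negative differences.

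Of 29 lists, camera called 7 in untreated cells, and each had an adjusted p of 0.696 with an estimated correlation. Proliferation was lower (median -0.72, adjusted p = 2.3e-09). ERK output (0.00168; 2 genes higher adjusted over the list alone), adhesion (0.00168), eosinophil identity (0.00534), interferon-stimulated genes (0.0121), type 2 activation (0.0153; 2 adjusted over the list alone) and other MAP kinase phosphatases (0.0181) were higher. With the proliferation score of the array as a covariate, which was added after the mice were seen to differ in it, only type 2 activation and other MAP kinase phosphatases of these 7 were still called, and the ERK output median went from 0.19 to 0.07 (adjusted p = 0.156). An exact permutation of the genotype over the 10 mice called 0 lists (smallest adjusted p 0.329), and 1517 genes had an unadjusted p under 0.05 in limma. The mean of the proliferation list over both arrays of a mouse was 8.77 ± 0.63 (SD, n = 5) in wild-type and 7.98 ± 0.45 in knockout mice, with an exact permutation p of 0.0635. The count of 3 rose to 15 without untreated wild-type array 2 and to 5 without untreated knockout array 5.

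After IL-33, the comparison asks what loss of Dusp5 does in stimulated cells. Genes that ERK switches on, and several cytokines, were higher in knockout cells. Egr1 was higher by 1.52 ± 0.18 (adjusted p = 1.8e-04) and Egr3 by 1.60 ± 0.27 (0.0066). The eosinophil survival factor Csf2, which encodes GM-CSF, was higher by 1.70 ± 0.26 (0.0023) and Il13 by 1.36 ± 0.24 (0.0087). Next to them stood 4833407H14Rik (1.82 ± 0.20) and Tmem267 (1.37 ± 0.18), then Retnla (1.12 ± 0.27), the adhesion scaffold Cass4 (1.07 ± 0.19), Il1a (1.03 ± 0.22) and the RNA helicase Ddx6 (0.97 ± 0.20). Beside Dusp5 (-4.82 ± 0.17), the largest deficits were Eri2 (-1.00 ± 0.24), the DNA repair gene Palb2 (-0.85 ± 0.19), the cell cycle repressor E2f8 (-0.84 ± 0.18), Csrp2 (-0.83 ± 0.21) and the atypical MAP kinase Mapk4 (-0.82 ± 0.17). Rnd1, Sap30, Slc45a3 and the mitochondrial enzyme Pck2 were lower by 0.68 to 0.74.

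In all, 260 genes passed, 116 higher and 144 lower in knockout cells, 11 of them at least 2-fold. With each mouse as a random block 514 genes passed. The split turned with the scaling, to 151 higher and 72 lower after a further quantile normalization and 93 higher and 68 lower after median centring.

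Of 19 ERK output genes 9 were higher, or 11 adjusted over the list alone (adjusted p = 7.7e-12). Beside the Egr genes they included Dusp6 (0.96 ± 0.23) and Spred2 (0.89 ± 0.16), both inhibitors of the ERK pathway. Of 16 cytokines 7 were higher, 12 adjusted over the list alone (3.4e-11), with Osm, oncostatin M, at 0.94 ± 0.13. Of 9 STAT genes 3 were higher, 7 adjusted over the list alone (2.8e-07), among them Cish (0.61 ± 0.12) and Pim3 (0.59 ± 0.15). These 3 lists each kept adjusted p = 0.0409 with an estimated correlation. The other 8 lists that camera called (adjusted p from 1.2e-07 to 0.0277) had adjusted p of 0.25 to 0.40 with an estimated correlation. They were NADPH oxidase and antioxidants (1 of 13, Hmox1 at 0.52 ± 0.12; 3 adjusted over the list alone), adhesion (2 of 16, Cd69 at 0.75 ± 0.16 and Cd9 at 0.38 ± 0.09; 3 alone), NF-kB (1 of 19, Rel at 0.71 ± 0.13; 4 alone) and tissue remodelling (0 of 13 in limma; 2 alone). The rest were chemokines (1 of 15, Ccl4 at 0.74 ± 0.14), eosinophil identity (0 of 13 in limma; 1 higher and 1 lower alone), other MAP kinase phosphatases (2 of 9, Dusp6 and Dusp2 at 0.61 ± 0.14; 3 alone) and proliferation. Of the 21 proliferation genes 0 passed over all genes and 21 were lower adjusted over the list alone (adjusted p = 1.2e-07; adjusted p = 0.400 with an estimated correlation), with Rrm2 at -1.08 ± 0.38 and Mki67 at -1.01 ± 0.37. An exact permutation of the genotype over the 10 mice called 0 of the 29 lists. Adjusted p was 0.0921 for the ERK, cytokine, STAT, NF-kB and stem and progenitor lists. Unadjusted, the ERK and cytokine lists had p = 0.00794, the smallest the permutations can give, and the other lists named here 0.0159. Adjusted over 29 lists, that smallest p passes only if several lists reach it, so this is not evidence against a difference.

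Other named genes were spread over lists that did not pass camera in the main fit. The pro-apoptotic Bcl2l11 was higher by 0.78 ± 0.13, the phospholipase Pla2g4a by 0.54 ± 0.12 and Pdcd1lg2 by 0.49 ± 0.10. Hoxa9 was lower by 0.58 ± 0.15, and its stem and progenitor list passed camera with no dim filter (adjusted p = 0.0424), quantile normalization (0.0294) and only the 2 groups (0.0226). The type 2 activation list of Pdcd1lg2 and the eicosanoid list of Pla2g4a passed with the filter at the 60th percentile (0.0459 each). Near Dusp5 on chromosome 19, Mirt1 (0.77 ± 0.15) and Smndc1 (0.45 ± 0.09) were higher and Mfsd13a was lower (-0.56 ± 0.14). Of the survival genes Bcl2 stood at 0.63 ± 0.18 (adjusted p = 0.062), and passed without IL-33 wild-type array 2 (0.00624), IL-33 knockout array 1 (0.0296) or untreated wild-type array 2 (0.0452), and with the filter at the 60th percentile (0.0462). Bcl2l1 stood at 0.21 ± 0.09 (0.14) and Mcl1 at 0.27 ± 0.15 (0.28). Ccr3 (0.53 ± 0.35), Siglecf (0.25 ± 0.15), Epx (-0.21 ± 0.18), Prg2 (-0.03 ± 0.06) and Il5ra (-0.49 ± 0.16) did not pass; without IL-33 wild-type array 2 Il5ra did (adjusted p = 0.0391), as did Mki67 (0.0196) and Rrm2 (0.0228).

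Single arrays moved the count of 260. It was 1659 without IL-33 wild-type array 2 and 1049 without IL-33 knockout array 1, but 47, 60, 49 and 33 without IL-33 wild-type array 1, 3, 4 or 5. It was 82, 55, 61 and 56 without IL-33 knockout array 2, 3, 4 or 5, 158, 161 and 163 without untreated wild-type array 1, 4 or 5, and 167 without untreated knockout array 4. With the proliferation covariate 18 genes passed, 16 of them among the 260. They included Dusp5, 4833407H14Rik, Egr1, Osm, Tmem267, Cass4 and Csf2, and 31 of the 38 passing genes named here no longer passed. At least 0.5 of the log2 difference was left in 22 of the 31, as for Mirt1 (0.78 ± 0.18), Pim3 (0.72 ± 0.17) and Dusp2 (0.60 ± 0.17), and less in 9, as for Dusp6 (0.44 ± 0.15), Eri2 (-0.36 ± 0.08) and Csrp2 (-0.29 ± 0.11). If the genotype itself alters proliferation, the covariate takes off part of the genotype's effect.

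**Figure D3:**
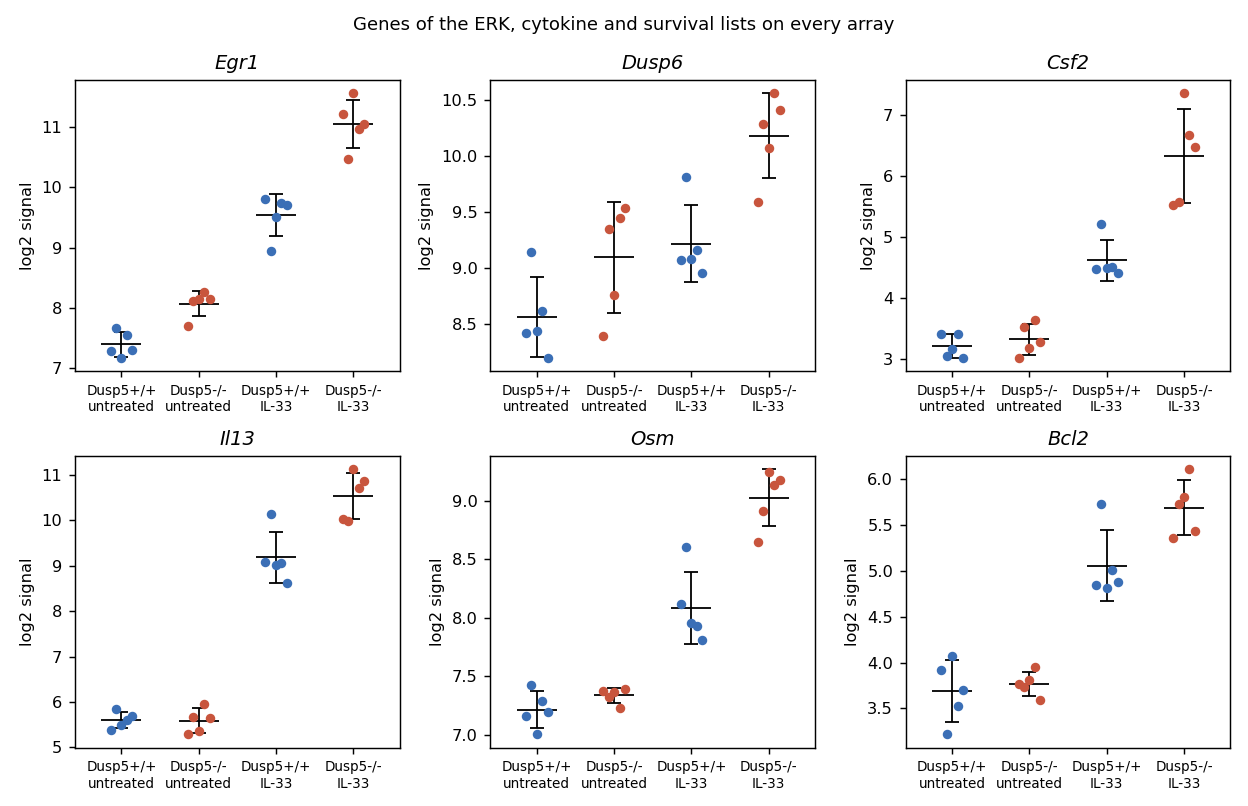
Log2 signal of Egr1, Dusp6, Csf2, Il13, Osm and Bcl2 on each array, by group, with the mean and SD of 5 arrays. After IL-33 the knockout means of the first 5 lie above the wild-type means by 0.94 to 1.70, and that of Bcl2 by 0.63, which did not pass.

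The last comparison, the interaction, tested whether the IL-33 response itself differed between the genotypes. No single gene passed with all arrays, equal array weights and no block. The genes named here therefore come from the fixed lists and the genes always named, not from a ranking of all genes. The response was larger in knockout cells by 1.59 ± 0.37 for Csf2, 1.37 ± 0.34 for Il13, 0.86 ± 0.16 for the AP-1 gene Fosl1, 0.84 ± 0.25 for Egr1 and 0.82 ± 0.18 for Osm. For Csf2, 9 of 10 untreated arrays lay below the percentile of the dim filter, so its difference rests on the IL-33 arrays, and it was 1.70 with dim arrays set to that percentile. The difference for Dusp5 was -1.07 ± 0.23. Pim3 (0.62 ± 0.21), Rel (0.58 ± 0.19), Ptgs2 (0.77 ± 0.36, with 8 of 10 untreated arrays below that percentile), Bcl2 (0.55 ± 0.25) and Bcl2l1 (0.09 ± 0.12) were further from passing. Over all genes limma called 0 (smallest adjusted p 0.282; 568 genes at an unadjusted p under 0.05). With each mouse as a random block it called 26, among them Fosl1 (adjusted p = 0.00960), Osm and Dusp5 (0.0222 each) and Csf2 and Il13 (0.0346 each), and as a fixed block 0. With array weights 2 passed, Fosl1 and Osm (0.0321 each). Without IL-33 wild-type array 2 the count was 3, namely Il13, Fosl1 (0.0484 each) and Osm (0.0460).

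By gene list, the change per mouse was compared between the genotypes. Averaged over the 16 cytokines, IL-33 raised the level by 2.28 ± 0.17 (SD, n = 5) in knockout and 1.83 ± 0.09 in wild-type mice, a difference of 0.454. For ERK output genes the means were 1.28 ± 0.16 and 0.99 ± 0.04 (difference 0.289), and for STAT genes 2.62 ± 0.13 and 2.32 ± 0.06 (difference 0.30). NF-kB genes (0.186) and NADPH oxidase and antioxidant genes (0.121) also rose more in knockout mice. The change was lower in knockout mice for stem and progenitor markers (-0.200) and for erythroid and megakaryocyte markers (-0.110). Neither of these 2 lists passed camera for IL-33 in the main fit in either genotype. With no dim filter the stem and progenitor markers did (adjusted p = 0.0452 in wild-type and 0.0267 in knockout cells). In an exact two-sided permutation test of the genotype over the 10 mice, each of the 7 lists given here had p = 0.00794, the smallest p the permutations can give, and an adjusted p of 0.0329. Camera called 5 of them with the preset correlation, from 1.0e-09 for cytokines to 0.0151 for NADPH oxidase and antioxidants, and none with an estimated correlation. With an estimated correlation the adjusted p was 0.0732 for cytokines and STAT genes, 0.142 for ERK output, 0.160 for NF-kB and 0.805 for NADPH oxidase and antioxidants. Adjusted over the list alone, 5 cytokines, 5 ERK output genes, 4 STAT genes and 1 tissue remodelling gene passed. Camera gave the other 24 lists adjusted p of 0.167 or more, and with each mouse as a fixed block called proliferation (4.4e-04) and neutrophil markers (0.0186) too.

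The size of the whole response was summarised per array as the mean of 2822 genes that rose minus the mean of 4492 genes that fell, chosen on both genotypes together. IL-33 moved this score by 0.946 ± 0.053 (SD, n = 5) in wild-type and 1.115 ± 0.062 in knockout mice. The difference was 0.168, which put the knockout change at 117.8% of the wild-type change, with 5 of 5 knockout mice above all wild-type mice (exact permutation p = 0.00794, the smallest the permutations can give). In untreated cells the score differed by 0.0415 (exact permutation p = 0.0794).

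**Figure D4:**
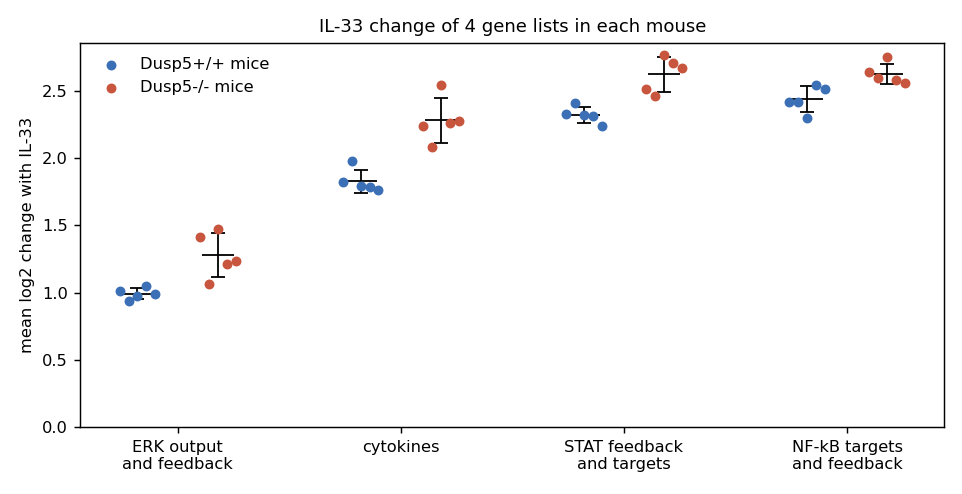
Change in the mean log2 level of 4 gene lists with IL-33 in each mouse, by genotype, with the mean and SD of 5 mice. Knockout mice lie higher in each list, by 0.289 for ERK output, 0.454 for cytokines, 0.30 for STAT genes and 0.186 for NF-kB genes.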

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

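Of the tests in this part, the chromosome of Tmem267, the genotype test of the proliferation score and the splits without Dusp5 were chosen after the results were seen.

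Each count of called genes was set against 100 splits of the same arrays drawn from 126. The IL-33 counts exceeded every other split. In wild-type cells the real 5027 was matched by 1 split, itself, with 1957 as the highest of the others, and in knockout cells 6137 by 1, with 2433. Among the 14 splits that part all 5 mice's pairs, the highest of the others was 0 in both. For the genotype, 3 of 100 splits called at least the 3 genes found in untreated cells and 2 of 100 the 260 found after IL-33. Without Dusp5, which the genotype sets, 3 of 100 called at least the other 2 (highest of the others 2245). For the other 259 it was 2 of 100 (2550). Both shares lie under 0.05, unadjusted for the several counts. They do not exclude chance as the source, since the mice of the genotypes also differed in proliferation genes (exact permutation p = 0.0635). The count after IL-33 still ran from 24 to 2094 without 1 mouse, and 1 split called far more, 2245 and 2551 genes. That split exchanged wild-type mouse 2 with knockout mouse 1, which points to a structure of the samples beside the genotype and parts the mice by their proliferation genes. The interaction's 0 calls are matched by any split (100 of 100, with 3 as the highest), so its count says nothing about chance.

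The first pattern is the rise of 4833407H14Rik and Tmem267 in untreated knockout cells. If DNA of another strain had been carried along with the targeted allele, genes within 10 Mb of Dusp5 would differ more often than others. For Tmem267 such linked DNA is argued against, since it lies on chromosome 13, not 19. Differing proliferation is argued against for both genes, since at least 0.753 of each log2 difference was left with the proliferation score as a covariate (4833407H14Rik 1.24 ± 0.10, Tmem267 1.33 ± 0.19). Carried-over DNA stays open otherwise. Untreated, 12.6% of the genes around Dusp5 had an unadjusted p under 0.05 (95% Clopper-Pearson interval 6.90% to 20.6%), against 12.9% of others (one-sided Fisher exact p = 0.575). Around Tmem267 it was 8% (0.984% to 26.0%; exact p = 0.850), and after IL-33 32% against 24.1% (exact p = 0.238), too few genes to decide. Whether the genotypes share a background strain or litters is not given in the sources used here. A local effect of the targeted allele on a nearby gene, or loss of Dusp5 itself, may also account for 4833407H14Rik and was not tested.

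The second pattern is the spread of proliferation genes between mice, from 7.56 to 9.42 in the list mean, which all 3 tests leave open. For RNA quality, the score's Spearman rho with the 5' control level over 10 mice was -0.321 (permutation p = 0.369), outside the range that would exclude it. For a changing share of other cell types, the 5 marker lists had rho down to -0.564 (monocytes, macrophages and dendritic cells) and none above 0.3, too weak to decide. For the genotype, the exact permutation p was 0.0635 (knockout minus wild type -0.785), so the difference between genotypes cannot be told apart from chance differences between mice. Wild-type mouse 2, at 7.79, lay among the knockout mice on this score, while its Dusp5 level was the highest of the wild-type mice.

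The third pattern is the larger rise of the cytokine and ERK lists in knockout cells. Differing proliferation is argued against, since with the mouse's score as a covariate at least 0.925 of each difference was left. The IL-33 change of the 5' controls differed by 0.0357 (exact permutation p = 0.579). That cannot decide on RNA quality, since a 5' level without its 3' counterpart also follows expression and scaling. A single factor on all IL-33 changes cannot be told apart. With the wild-type change times the slope of 1.15 taken off, the ERK list lay above (median 0.0992, camera adjusted p = 0.0197). The cytokines did not pass (median -0.00411, camera adjusted p = 0.0624). NF-kB genes (median -0.27, 9.9e-04), chemokines (-0.175, 0.0197) and type 2 activation genes (-0.177, 0.0232) lay below. With an estimated correlation none of the 5 passed (0.941 each), which keeps it open. A specific effect on ERK targets and a general gain of the response are therefore both candidate explanations.

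The change per mouse with IL-33 differed between the genotypes, knockout minus wild type, by 0.168 for the response score and by 0.289 for ERK output, 0.454 for cytokines, 0.186 for NF-kB, 0.30 for STAT, 0.121 for NADPH oxidase and antioxidant, -0.110 for erythroid and -0.200 for stem and progenitor genes (exact permutation p = 0.00794 each, the smallest the permutations can give).

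Probe sets without a single gene name, which no comparison uses, numbered 1114 above the filter. Of these 278 were called for IL-33 in wild-type cells, 368 in knockout cells, 13 for the genotype after IL-33 and 1 in the interaction.

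Single arrays stood apart from the other 4 of their group in 30 of 444 gene and group combinations, where chance gives 22.2. Of the 30, 16 were arrays of wild-type mouse 2. The gap to the nearest array, as a share of the group's range, is given for each. In untreated wild-type cells array 2 was high for Egr2 (0.835), Cxcl3 (0.808) and Zc3h12a (0.808) and low for Insig1 (0.781), Prg2 (0.773), Csrp2 (0.736) and Chil1 (0.711), and array 3 was high for Sap30 (0.771) and Car2 (0.716). In wild-type cells with IL-33 array 2 was high for Csf2 (0.892), Spred2 (0.825), Pdcd1lg2 (0.797), Cxcl2 (0.79), Bcl2 (0.785) and Dusp6 (0.768) and low for Sap30 (0.725), Epx (0.714) and Insig1 (0.712). There, array 3 was high for Bcl2l1 (0.822) and array 1 for Timp1 (0.788). In untreated knockout cells array 5 was high for Traf1 (0.804), array 1 was high for Fzd2 (0.768) and low for Egr1 (0.746) and Bcl2l1 (0.744), and array 3 was low for Bmf (0.794). In knockout cells with IL-33 array 3 was low for Bmf (0.826) and high for Acod1 (0.734), array 1 was low for Cd9 (0.757) and high for Rnd1 (0.754), and array 4 was high for Dusp16 (0.738).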

How the results depend on the processing

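The proliferation covariate, leaving out both arrays of a mouse and the exact permutation of lists were chosen after the data were seen; the cause of each change below was not tested unless stated. Dusp5 kept its direction in every comparison and alternative run, as did the response score (0.143 to 0.185 without 1 mouse). Of the passing genes named, 68 of 70 for IL-33 in wild-type cells, 33 of 34 in knockout cells and 3 of 3 in untreated cells kept their call in every alternative that tested them, against 6 of 38 after IL-33 (Dusp5, 4833407H14Rik, Tmem267, Egr1, Osm and Cass4; the filter at the 60th percentile left Tmem267 out); none reversed. Of those 38, 31 lost it with the proliferation covariate, 30 with only the 2 groups compared, which leaves fewer arrays, and up to 29 without 1 mouse. Values near the arrays' floor limit folds of dim genes.

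Counts of genes that moved were, at 1.5-fold or more, 1613 and 2233 for IL-33 in wild-type and knockout cells and 72 for the genotype after IL-33. That last count was 23 at an adjusted p under 0.01, 152 with no filter (more genes tested), 444 with a filter at the 60th percentile (fewer genes tested), 161 with median centring, 24 with only the 2 groups and 18 with the proliferation covariate. Array weights gave 1466 untreated (with Egr3, adjusted p = 0.00547, and Egr1, Rrm2, Dusp6, Mki67, Ccr3 and Mcl1, 0.0225 to 0.0417), 2321 after IL-33 (with Bcl2, 0.00703, and Rrm2, Mki67, Il5ra and Bcl2l1, 0.0106 to 0.0426) and 2 in the interaction, and 12 lists untreated, and Mcl1 passed for IL-33 in wild type (0.0251). Without Dusp5 and its neighbours, 1 gene was left untreated.

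With each mouse as a random block, 514 genes passed after IL-33 and 26 in the interaction, where Dusp5 passed at -1.065 (adjusted p = 0.0222). Beyond the calls given here and with the results, the replicate block within genotype changed no call of a named gene or list. Across genotypes same-numbered arrays correlated at -0.168 to 0.601 untreated and -0.181 to 0.562 with IL-33, only 1 and 3 of 5 best with their own number, so the number marks no shared unit there. That replicate block, across genotypes, gave 806 genes and 12 lists untreated and 2187 genes after IL-33.

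Lists called (10, 9, 7, 11 and 5 with camera's preset, in the order IL-33 in wild type, in knockout, genotype untreated, after IL-33, interaction) numbered 5, 5, 0, 3 and 0 with an estimated correlation and 18, 18, 0, 7 and 0 with fry, which tests each list on its own. Exact permutation over mice called 0 untreated and 0 after IL-33. The random mouse block called 13, 11, 10, 13 and 5, adding chemokines, tissue remodelling and NADPH oxidase genes untreated (0.0212 to 0.0376) and type 2 activation (0.0492) and stem and progenitor markers (0.0428) after IL-33. The proliferation score was lower after IL-33 in all 10 mice, so with it as a covariate the slope between mice enters the IL-33 comparisons and the interaction, which then measure more than IL-33. With it the ERK, cytokine, STAT and NADPH oxidase lists were still called after IL-33, while the proliferation list (by construction), chemokines, NF-kB, tissue remodelling, other MAP kinase phosphatases, eosinophil identity and adhesion were not (adjusted p from 0.0678 to 0.809). Untreated, it ended the calls of ERK output (0.156), interferon-stimulated genes (0.273), eosinophil identity (0.491), proliferation (0.898) and adhesion (0.913), and it newly called 5 lists untreated and 5 after IL-33, cholesterol synthesis first (0.00105 and 3.5e-05). For IL-33 it ended those of other MAP kinase phosphatases in wild type (0.0832) and adhesion in wild type (0.0953) and knockout (0.170). The call of the other MAP kinase phosphatases after IL-33 ended without IL-33 array 5 of either genotype (0.0875 and 0.0784), and that of NADPH oxidase and antioxidants in the interaction without untreated wild-type array 1 or 2 or IL-33 wild-type array 3 (up to 0.333), with quantile normalization (0.106) and with the proliferation covariate (0.150). Untreated, interferon-stimulated genes lost theirs without wild-type array 5 or knockout array 2 (up to 0.107), type 2 activation without wild-type array 4 (0.0650) and other MAP kinase phosphatases without knockout array 5 (0.0677) or wild-type mouse 4 (0.0536).

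Genes whose sign reversed had not passed, but called lists reversed too. With quantile normalization Prg2 was at -0.041 and the adhesion list at 0.0763 for IL-33 in knockout cells. With the proliferation covariate Epx was at 0.193 and 0.239 for IL-33 in wild-type and knockout cells (the second passed, adjusted p = 0.0356, as did Ccr3 at -0.773 and -1.087), 0.173 for the genotype untreated and 0.219 after IL-33. Prg2 was then at 0.062 for IL-33 in wild type, 0.0359 untreated and 0.0748 after IL-33, Mcl1 at -0.00461 untreated and -0.0999 after, Bcl2 at -0.0235 untreated and Ccr3 at -0.306 after. The adhesion list went to -0.071 for IL-33 in wild type, from 0.193 to -0.00194 untreated and from 0.153 to -0.0484 after, and the identity list from 0.253 to -0.0296 after.

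Without 1 array or mouse, the count after IL-33 ran from 24 (wild-type mouse 5) to 2094 (wild-type mouse 2), with 28, 67 and 42 without wild-type mouse 1, 3 or 4 and 1167, 65, 53, 30 and 31 without knockout mouse 1 to 5. Untreated it ran from 3 to 651 (without wild-type mouse 2), and lists from 7 to 14 (the same mouse). The interaction ran from 0 to 3 genes and 4 to 9 lists (without IL-33 wild-type array 2). Dusp5 for IL-33 in knockout cells ran from 0.412 (without mouse 5, adjusted p = 0.0668) to 0.669. For IL-33 in wild type Epx ran from -0.18 to 0.103, Prg2 from -0.0501 to 0.0321 and the adhesion list from -0.036 to 0.17. In knockout cells Epx ran from -0.164 to 0.0138 and the adhesion list from -0.0936 to 0.0542, and Bcl2 untreated from -0.039 to 0.175.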

Other observations

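The maturation test in this part was chosen after the result was seen, as were the neighbouring genes.

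The proliferation list held its place before and after IL-33, with a Pearson r of 0.996 and a Spearman rho of 1 between the untreated and IL-33 arrays of the 10 mice (permutation p = 1e-05). Mice with high proliferation genes had more granule protein message and a lower mean of the eosinophil identity and receptor list (the receptor list below). That list also holds transcription factors. Its member Il5ra stood lower in knockout cells without passing in the main fit, and its own relation with proliferation was not tested. Wild-type mouse 3, the highest at 9.42, had a granule protein mean of 13.6 and a receptor mean of 8.94, and knockout mouse 2, the lowest at 7.56, had 13.1 and 9.47. Over the mice, the granule protein list went with the proliferation list at r = 0.916 and rho = 0.891 (adjusted permutation p = 9.8e-04 and 0.00407), and r was 0.841 without the 2 mice farthest from the median. The unfolded protein and integrated stress response list did so at r = 0.911 and rho = 0.952 (adjusted p = 5.6e-04 and 0.00208; 0.868 without those mice). The adhesion list ran the other way, at r = -0.931 and rho = -0.867 (adjusted p = 5.6e-04 and 0.0077; -0.868). Glycolysis (r = 0.658, rho = 0.661) and cholesterol synthesis (r = 0.739, rho = 0.648) did not pass after adjustment over the 13 relations computed (adjusted p of 0.0611 or more).

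A hypothesis is that the cultures had reached different stages of eosinophil maturation by the day of the experiment, since precursors divide and transcribe granule protein genes while receptors and adhesion molecules come later. It requires the receptor list to fall as the proliferation list rises, and rho over the 10 mice was -0.927 (r = -0.942, adjusted permutation p = 0.00306 and 5.6e-04; r = -0.933 without the 2 farthest mice). These values are consistent with that hypothesis, which was found and tested on the same mice. Stem and progenitor markers, which a less mature culture could also keep, gave no such relation (r = 0.487, rho = 0.43, adjusted permutation p = 0.23 and 0.354; r = -0.000897 without the 2 farthest mice). The 5 knockout mice held 4 of the 5 lowest proliferation scores, so a stage that differs by chance between mice and one that differs by genotype are both open (exact permutation p = 0.0635).

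On one side of Dusp5, the span of Mirt1 in the GRCm38.p6 annotation holds 4833407H14Rik, so these 2 may not be separate signals. Smndc1 is the next tested gene on that side. After IL-33, 4833407H14Rik, Mirt1 and Smndc1 were all higher in knockout cells (1.82 ± 0.20, 0.77 ± 0.15 and 0.45 ± 0.09). Beyond Smndc1, Mxi1 (-0.08 ± 0.07) did not pass after IL-33, nor did the nearest tested gene on the other side, Smc3 (0.04 ± 0.13). In untreated cells Mirt1 (0.415 ± 0.155, limma adjusted p = 0.383) and Smndc1 (0.15 ± 0.09, 0.454) did not pass either. Near Tmem267 on chromosome 13, Nnt, a mitochondrial transhydrogenase gene known to differ between laboratory mouse substrains, was lower in knockout cells after IL-33 (-0.31 ± 0.07, adjusted p = 0.024) and stood at -0.02 ± 0.07 untreated.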
